A study of Caenorhabditis elegans with 4 samples.

How the data were processed

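Sites bound by a GFP-tagged factor, named ZTF-11 in the titles and ekl-2 in the genotype, were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Caenorhabditis elegans embryos. ZTF-11 is a zinc finger transcription factor of the MYT1 family, which acts in neurogenesis; the labels do not say whether ekl-2 is the same gene. Per the labels, the strain carries a transgene that fuses the factor to GFP, and the culture was a mixture of males and hermaphrodites. Per the labels' protocols, worms were grown at 20 °C and crosslinked with 2% formaldehyde, the chromatin was sonicated, and complexes were collected with anti-GFP antibodies. A part of each lysate was kept as input DNA. The series holds 4 samples, made up of 2 ChIP replicates and 2 input replicates. The labels number the replicates but do not say whether they came from separate cultures, so the agreement between them may be partly technical.

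The files analysed were 3 peak lists deposited by the authors, 1 for each ChIP replicate and 1 for the combination of both. Per the file headers, positions are on the WormBase WS180 build, and the source column names PeakSeq as the peak caller. The unit of the only measured value is a q-value per peak, deposited by the authors in the score column and repeated in the attribute column. Neither the aligner, the PeakSeq version and settings, the way the replicates were combined, nor the use of the input in peak calling is given in the sources used here. No list file holds read counts, so the sequencing depth is unknown. No signal in the input samples was analysed here, and no background level could be set beside the peaks. A q-value mixes the strength of enrichment with the number of reads, so it was used, as −log10 q, to rank or describe peaks inside its own list. Where q-values of several lists stand side by side, no change in binding is read from them.

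The peaks have no summit, so the midpoint was used. A peak counted as found in another list if it overlapped a peak of that list by 1 bp or more. Shares have 95% Wilson intervals, which cover counting error only and treat peaks as independent. The overlap of the replicates was compared with 10000 random placements in which the other list was shifted around each chromosome by at least 10 kb, giving a one-sided permutation p. The difference in median −log10 q between combined peaks found in both replicates and the rest was tested with a two-sided permutation test of 100000 resamples. Spearman's and Pearson's coefficients for −log10 q were computed across shared peaks with permutation p-values of 100000 resamples. Shared peaks are not independent replicates.

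The planned expectation for each chromosome was its length. Lengths of the WS180 chromosomes were not used here, and the highest peak end over the 3 lists stood in for each length. Counts per chromosome were tested against that span with a two-sided exact binomial test, Benjamini-Hochberg adjusted over the 6 chromosomes. Protein-coding gene numbers per chromosome from the RefSeq table of assembly WBcel235 served as another expectation. Close neighbours were peaks under 5 kb apart, edge to edge, compared with 10000 uniform placements within each chromosome. A run was a set of peaks each under 10 kb from the next. The neighbour test, the runs and the agreement of q-values were added after the data had been examined.

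Because the gene table is on another build than the peaks, and positions were not converted between builds, no peak was assigned to a gene. Of the planned results, 4 were not run. The share of peaks near transcription starts, the gene lists and the non-coding RNA genes needed gene positions on WS180, and the sequence motifs needed a genome sequence, which was not used here. The rule for named genes covered the tagged gene, unc-119 and the genes at the 20 strongest peaks. Its provision for a missing annotation was applied, and the 20 combined peaks with the smallest q are named by position. The tagged gene and unc-119 were not located on WS180 and have no value here.

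The overlap test was checked on simulated lists. With 100 of 197 peaks made to overlap, 101 were found. For the chromosome test on 542 simulated peaks, an X excess of 1.3 gave a p below 0.05 in 69.6% of 500 simulated lists, an excess of 1.6 in 99.6%, and no excess in 4.4%. The simulated peaks were drawn independently of each other, so this check does not cover peaks that lie in runs. Alternatives to the overlap rule, the peak threshold, the random placement, the expectation per chromosome and the replicates used were fixed before the data were examined, apart from those named as added. Alternatives used 1000 random placements and 10000 resamples. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.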

Results

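ChIP-seq of the GFP-tagged factor labelled ZTF-11 in embryos gave 3 deposited peak lists. The study mapped the sites that the factor occupied in vivo. The series title and strain text name the tagged protein ZTF-11, whereas the genotype names the transgene ekl-2. The labels do not say whether these are names of 1 gene. The plan for the named genes treated ekl-2 as another name of ztf-11, and the tagged protein is called ZTF-11 here as the title gives it. The combined list held 542 peaks, replicate 1 held 197 and replicate 2 held 146. Median peak widths were 407.5 bp, 390.0 bp and 414.5 bp, and the lists covered 269.7 kb, 94.9 kb and 71.3 kb. The largest q-value in each list was 7.86e-05, 5.84e-05 and 5.30e-05. Read depth was unknown, and the input samples entered no comparison.

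The strongest site lay on chromosome IV from 14032522 to 14034910 (WS180). It had the smallest q-value in all 3 lists, 8.76e-70 in the combined list, 2.20e-40 in replicate 1 and 2.43e-34 in replicate 2, and it was 2389 bp wide. The next combined peak, on I from 9988662 to 9989172, was 511 bp wide, with q = 5.18e-37. The third, on II from 14249310 to 14251857, was the widest peak of the list at 2548 bp and had q = 1.39e-36. Replicate peaks inside that interval were shorter, for example 14251301 to 14251845 in replicate 1 (q = 4.72e-08) and 14251028 to 14251797 in replicate 2 (q = 1.75e-08). The fourth peak was on IV from 8333902 to 8334720, with q = 1.98e-33.

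The 20 strongest combined peaks comprised 6 on X, 5 on IV, 3 on III, 3 on V, 2 on I and 1 on II, and each of the 20 was found in both replicates. On X these were 11604998 to 11606534 (q = 3.11e-30), 10568210 to 10569174 (q = 3.01e-27), 4209089 to 4209451 (q = 1.34e-24), 11093885 to 11094335 (q = 1.46e-23), 16929418 to 16930502 (q = 1.36e-22) and 12691647 to 12693765 (q = 4.78e-21). On III they were 10461019 to 10461399 (q = 4.12e-28), 13070341 to 13071082 (q = 8.16e-25) and 10758944 to 10759358 (q = 2.10e-22). The other 3 on IV were 16491451 to 16492850 (q = 7.88e-23), 7486166 to 7486598 (q = 1.47e-21) and 11025749 to 11026405 (q = 3.19e-21). On V they were 9343129 to 9344490 (q = 2.02e-23), 16040444 to 16040822 (q = 8.79e-23) and 1151303 to 1152126 (q = 3.27e-21), and the other peak on I was 4171926 to 4172610 (q = 2.07e-20). Of these 20 peaks, 7 were wider than 1 kb, against 33 of all 542. Across the combined peaks, width and −log10 q were correlated with a Spearman coefficient of 0.46 (permutation p = 0.0001, the smallest the permutations can give). A q-value also depends on the number of reads, and a wider peak can hold more of them. The coefficient therefore does not show that wide sites were more strongly bound.

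The replicate lists were then compared to see which sites recurred. Of the 197 replicate 1 peaks, 113 overlapped a replicate 2 peak, a share of 57.4% (95% Wilson interval 50.4 to 64.1%). Of the 146 replicate 2 peaks, 114 overlapped a replicate 1 peak, a share of 78.1% (70.7 to 84.0%). Shifted lists gave a mean of 0.33 overlapping replicate 1 peaks and at most 5, and the one-sided permutation p was 0.0001, the smallest that 10000 shifts can give. The 32 strongest peaks of replicate 1 all recurred, and the first without a partner ranked 33, with q = 7.74e-10. In replicate 2 the first such peak ranked 55, with q = 1.56e-07. Among peaks without a partner, 80 of 84 from replicate 1 and 30 of 32 from replicate 2 still overlapped a combined peak.

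Sites that were strong in replicate 1 tended to be strong in replicate 2. Over the 113 shared peaks, −log10 q had a Spearman coefficient of 0.62 and a Pearson coefficient of 0.86 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Without the peak on IV at 14032522 the Spearman coefficient was 0.61. That peak lay far from the rest, at −log10 q of 39.7 in replicate 1, where the next shared peak had 19.5. The Pearson coefficient depends on such distances, and its value without that peak is not given here. These coefficients run across peaks of one pair of samples, and peaks are not independent replicates.

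**Figure D1:**
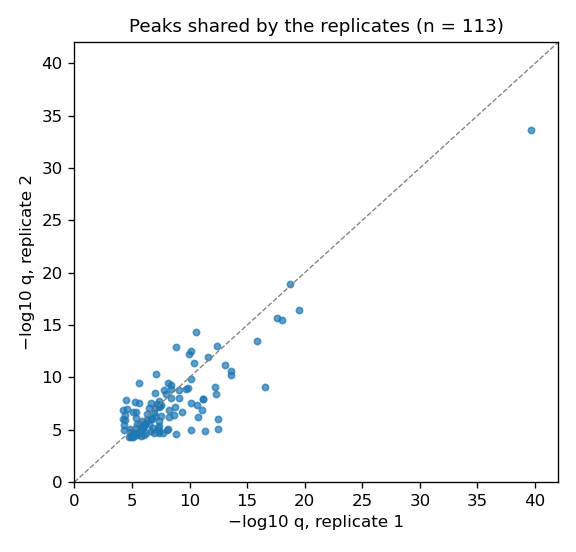
Each point is 1 of the 113 replicate 1 peaks that overlap a replicate 2 peak, placed by −log10 q in replicate 1 (x axis) and replicate 2 (y axis); the dashed line marks equal values. The point at the upper right is the peak on IV at 14032522, and the Spearman coefficient is 0.62.

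The combined list was set against the replicates to see how much of it each carried alone. Of its 542 peaks, 113 (20.8%, 95% Wilson interval 17.6 to 24.5%) were found in both replicates, 79 in replicate 1 only and 30 in replicate 2 only. The other 320 (59.0%, 54.9 to 63.1%) were found in neither. The recurring share depended on rank. Both replicates held 48 of the first 50 combined peaks, 33 of the next 50, 23 of the 100 after those and 0 of the last 142 (upper Wilson limit 2.63%). The strongest combined peak absent from both replicate lists ranked 54 and lay on I from 5315795 to 5317005, with a width of 1211 bp and q = 4.31e-15.

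Median −log10 q was 13.5 for the 113 peaks found in both replicates and 5.57 for the other 429, a difference of 7.93 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The interquartile ranges were 10.1 to 17.3 and 4.67 to 6.82. The combined list drew on the same ChIP samples as the replicate lists, so this comparison is not independent evidence of recurrence.

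**Figure D2:**
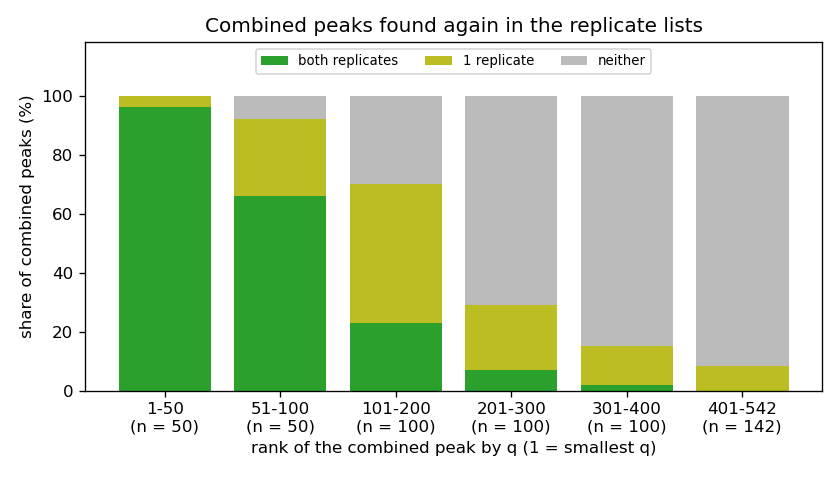
Stacked bars give the share (%) of combined peaks found in both replicates, in 1 replicate or in neither, by rank of q (x axis, number of peaks under each bar). Both replicates held 96.0% of the first 50 peaks and 0 of the last 142.

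Peaks were unevenly spread over the chromosomes. X carried 122 of the 542 combined peaks (22.5%, 95% Wilson interval 19.2 to 26.2%), 1.28 times the 95.4 expected from its share of the chromosome span (exact binomial adjusted p = 0.0079). Chromosome III carried 106 peaks (19.6%, 16.44 to 23.1%), 1.42 times the expected 74.8 (exact adjusted p = 0.00068). Chromosome V carried 73 (13.5%, 10.9 to 16.6%), 0.64 times the expected 113.7 (exact adjusted p = 5.18e-05). Chromosomes I, II and IV, with 63, 96 and 82 peaks, stood at 0.78, 1.15 and 0.87 times their expectation and did not pass the adjusted threshold (exact adjusted p = 0.052, 0.16 and 0.17). The ratio on II was 1.22 in replicate 1 and 0.80 in replicate 2 (exact adjusted p = 0.24 and 0.43).

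The same 3 chromosomes stood apart in each replicate. The replicate lists share most of their sites (113 of 197 replicate 1 peaks and 114 of 146 replicate 2 peaks), so their tests are not independent. X held 1.44 times its expected count in replicate 1 and 1.63 times in replicate 2 (exact binomial adjusted p = 0.013 and 0.0020). For III the ratios were 1.47 and 1.79 (exact adjusted p = 0.019 and 0.0019), and for V they were 0.58 and 0.59 (exact adjusted p = 0.0095 and 0.012). Chromosome I was also below expectation in both replicates, at 0.51 and 0.37 times (exact adjusted p = 0.010 and 0.0019). Among combined peaks, I held 6 of the 113 found in both replicates (5.31%) and 47 of the 320 found in neither (14.7%), a difference that passed Fisher's exact test after adjustment over 6 chromosomes (adjusted p = 0.044). The corresponding shares on X were 28.3% and 19.7% (Fisher exact adjusted p = 0.16). Among the 320 found in neither, X stood at 1.12 times its expectation (exact binomial adjusted p = 0.41) and I at 0.99 times, so neither stood apart there. In that set III stood at 1.38 and V at 0.66 times (exact binomial adjusted p = 0.028 and 0.0072). Among the stronger 50% of the combined list by q, X held 59 of 271 peaks, 1.24 times its expectation, with an unadjusted exact p of 0.079. Peaks in runs are not independent, and counting each run once left X at 1.34 times (unadjusted exact p = 0.0010).

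**Figure D3:**
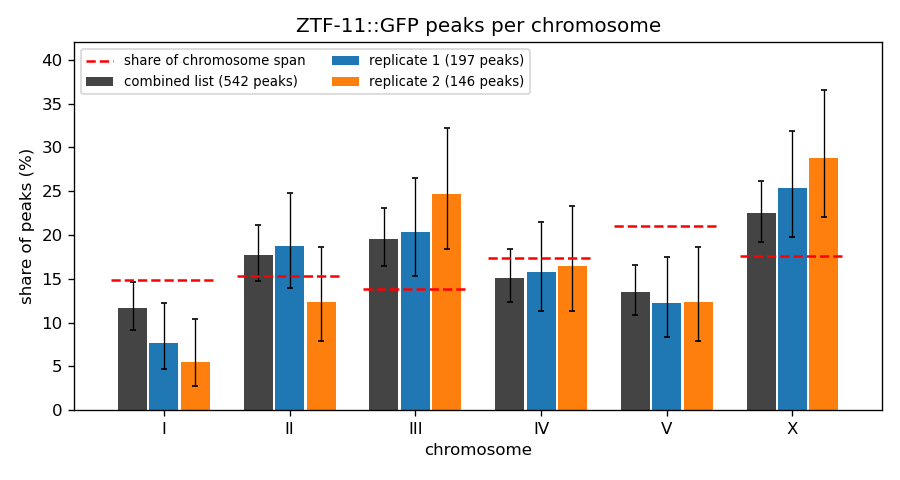
Bars give the share (%) of peaks on each chromosome in the combined list, replicate 1 and replicate 2, with 95% Wilson intervals; dashed lines give each chromosome's share of the peak span. In all 3 lists X and III lie above their line and I and V below it.

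Peaks also lay near each other more often than random placement gave. Of the 542 combined peaks, 94 (17.3%, 95% Wilson interval 14.4 to 20.8%) had another within 5 kb, against a mean of 33.5 and a maximum of 68 in 10000 placements (one-sided permutation p = 0.0001, the smallest they can give). The share was lower in the shorter lists, as was the random expectation, taken there from 1000 placements per list. It was 8.63% in replicate 1 (17 of 197, random mean 4.804 and maximum 17, permutation p = 0.0030), 10.3% in replicate 2 (15 of 146, mean 2.77 and maximum 11, permutation p = 0.0010, the smallest that 1000 placements can give) and 7.96% among combined peaks found in both replicates (9 of 113, mean 1.86 and maximum 10, permutation p = 0.0030). Of the 542 combined peaks, 40 had a neighbour under 1 kb away. The lists do not say whether such peaks are separate sites or parts of 1 enriched region. Uniform placement also lets peaks fall anywhere on a chromosome. The test therefore cannot tell clustering of sites from a restriction of peaks to certain stretches of DNA. There were 14 runs of at least 3 peaks, holding 47 peaks. Chromosome III had 6 of these runs, II had 5, X had 2 and IV had 1, while I and V had none. No random expectation for runs is given here, and denser peaks give more runs under random placement. III held 106 peaks over 13.7 Mb and V held 73 over 20.8 Mb, so the run counts are not a separate result on clustering.

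The longest run lay on III from 12598326 to 12616415 and held 5 peaks. Its strongest member, 12612327 to 12612867 (q = 1.50e-19), was found in both replicates. The weakest, 12598326 to 12598603 (q = 2.56e-06), was found in replicate 1. Both 12614610 to 12616415 (q = 2.52e-14) and 12608084 to 12608836 (q = 2.02e-12) were among the 3 members found in neither replicate. A run of 3 peaks on III from 8795381 to 8802310, with a smallest q of 4.82e-20, had every member found in both replicates. A run of 4 on II from 6827278 to 6839223, with a smallest q of 3.77e-07, had no member found in either.

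**Figure D4:**
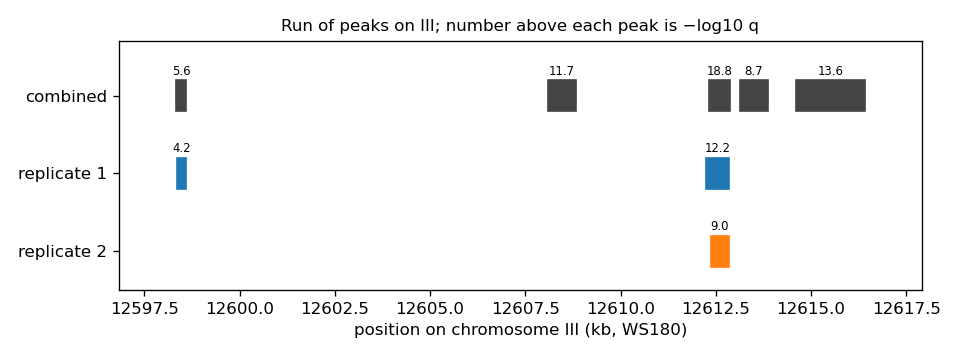
Boxes mark the peaks of each list on chromosome III around the run from 12598326 to 12616415 (x axis in kb, WS180), to scale, with −log10 q above each. The combined list has 5 peaks there, replicate 1 has 2 and replicate 2 has 1.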

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

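Of 68 alternative values, 59 kept their direction and side of the threshold or, for shares without a test, stayed inside the main interval, and 2 reversed. Both were on chromosome II, whose ratio of 1.15 passed no test: it was 0.75 among peaks found in both replicates and ranged from 0.80 to 1.22 with replicate 1 or replicate 2 left out (unadjusted exact p = 0.30, 0.36 and 0.20); the cause was not tested. Requiring midpoints within 100 bp lowered the share of combined peaks found in at least 1 replicate from 41.0% to 36.3% and the share found in both from 20.8% to 16.05%; requiring an overlap of 50% of the shorter peak changed neither. With replicate 1 or replicate 2 left out, the share found ranged from 26.4% to 35.4%, since a single list then counts. The difference in median −log10 q between found peaks and the rest, 7.93 with both replicates, was 6.08 without replicate 1 and 4.98 without replicate 2. In the stronger 50% of the combined list by q the X ratio was 1.24 on 271 peaks, against 1.28 on 542, and no longer passed its test. The share on X there was 21.8% (95% Wilson interval 17.3 to 27.1%), and the interval includes the 22.5% of the full list. A weaker excess therefore cannot be told apart from an effect of fewer peaks. Over the other alternatives the X ratio ranged from 1.34 to 1.65, and the cause was not tested. The deficit on chromosome I (0.78, unadjusted exact p = 0.034) was 0.81 with gene numbers as the expectation and 0.82 with each run counted once, and passed neither test. The excess on III and the deficit on V passed in every alternative run. The share of peaks with a close neighbour (17.3% of combined peaks at 5 kb) was 7.38% at 1 kb, 31.9% at 20 kb, 7.96% among peaks found in both replicates, 10.3% in the replicate 2 list (without replicate 1) and 8.63% in the replicate 1 list (without replicate 2), each above its random mean. Shifts of 20 to 200 kb for the overlap, all alternatives for close neighbours (distances of 1 and 20 kb, shifts of up to 500 kb, other peak lists), counting runs once, the stronger 50% for the difference in −log10 q, and the 2 alternatives for the agreement of q-values were added after seeing the data. Alternatives for the 4 planned results that needed gene positions or sequence were not run. No paired analysis was possible because the input samples that share the replicate numbers have no peak list here. Depth is unknown, so whether a site missing from a replicate was unbound or undersampled cannot be decided from the lists.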

Other observations

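The tests on II, on peaks found in neither replicate, on q-values across lists and on peak edges, and the counting of runs were chosen after the data were seen. On autosomes, 240 of 420 combined peaks (57.1%, 95% Wilson interval 52.4 to 61.8%) lay in the central 50% of the span (exact binomial p = 0.0039). The test treats peaks as independent and was not repeated with each run counted once. Its expectation of 50% takes gene content and mappability as even along the chromosomes, which was not tested. This met the prediction of the hypothesis that sites are more frequent in autosome centres than towards the ends, but it passed the threshold only with chromosome V included. Each autosome lay above 50%, at 60.3% on I, 54.2% on II, 54.7% on III, 52.4% on IV and 67.1% on V. V had 49 of 73 peaks in its centre and alone passed on its own (exact binomial adjusted p = 0.028 over 6 chromosomes). Without V the share was 55.04% (95% Wilson interval 49.8 to 60.2%, exact p = 0.068). Among the 81 autosomal peaks found in both replicates it was 54.3% (43.5 to 64.7%, exact p = 0.51). Both intervals include 57.1%, so these smaller sets do not show whether V alone carried the pattern. X had 61 of 122 peaks in its centre (50.0%), and the difference between autosomes and X did not pass Fisher's exact test (p = 0.18).

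Chromosome II was lopsided. The leftmost 25% of its span, up to 3.82 Mb, held 8 combined peaks and the rightmost 25%, from 11.4 Mb, held 36 (exact binomial adjusted p = 0.00015 over 6 chromosomes); no other chromosome passed. Neighbouring peaks counted separately do not account for all of it, since 75.0% of the peaks in these outer parts were still on the right with each run counted once (24 against 8, exact adjusted p = 0.042). Whether weak peaks of the combined list account for it could not be decided. Of the 9 outer peaks found in both replicates, 88.9% lay on the right (8 against 1, exact p = 0.039, adjusted p = 0.23). Among the 271 strongest combined peaks by q, the counts on II were 18 against 5 (exact p = 0.011, adjusted p = 0.064). Both sets are part of the list that showed the pattern, and neither passed after adjustment. The counts were 19 against 2 in replicate 1 (exact adjusted p = 0.0013) and 9 against 2 in replicate 2 (adjusted p = 0.20). Uneven mappability or gene content along II stays open, and no biological explanation was tested.

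The excess on X was tested against 2 technical explanations. Neighbouring peaks counted separately would have removed the excess once runs were counted once, and the ratio was 1.34 (exact binomial p = 0.0010). Weak peaks of the combined list would have left the peaks found in both replicates without an excess, and their ratio was 1.61 (exact p = 0.0043), although the stronger 50% by q alone gave 1.24 (exact p = 0.079). Against gene numbers, an expectation that does not use the peak span, X stood at 1.65 (exact p = 2.82e-08); gene number is not length, so this does not measure an error in the span. The span, as the highest peak end, can fall short of the length only beyond the last peak. X held 17.6% of the span and would need 22.5% of the length to expect its share of combined peaks. From 13.1 Mb to the end of its span at 17.5 Mb, X held 32 combined peaks. These values argue against an error in the span as the source of the whole excess. Mappability stays open, as does a preference of the factor for X-linked sites, since no other factor was compared.

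For the 320 combined peaks found in neither replicate, less data per replicate than in the combination cannot be told apart from weak or false combined peaks. A combined peak found in a replicate had the smaller q in 0.893 of all comparisons with one found in neither (bootstrap 95% interval 0.866 to 0.920), which either explanation would give. Broad regions of low enrichment could not be decided: at like q, the median log2 width ratio of peaks found in neither to the others was -0.011 (interval -0.23 to 0.25; permutation p = 0.91, 330 peaks in 6 bins).

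The q-values of the combined list were smaller than those of either replicate at most recurring sites, but not at all. For the 113 combined peaks found in both replicates, −log10 q exceeded the better replicate by a median of 5.33. At 3 peaks, chosen after their values were seen, it was lower. The peak on I from 3171486 to 3172050 had q = 4.09e-13 and 9.89e-14 in the replicates and 2.43e-08 in the combined list. The peak on III from 931226 to 931821 had q = 3.06e-20 and 3.43e-17 in the replicates and 1.90e-15 in the combined list. The peak on V from 5284007 to 5285455 had q = 2.32e-14 in replicate 1 and 6.41e-14 in the combined list. How the q-values of the 3 lists relate is not given in the sources used here.

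The start at 3171486 on I was identical to the base in all 3 lists, as were the starts at 10461019 on III and 11070895 on IV. Over the 226 edges of shared peaks, 4 had an offset of 0 bp (one-sided exact Poisson p = 0.14). The mean was 2.0 at each single offset of 1 to 10 bp, with offsets to the left and to the right counted as separate offsets. The hypothesis that unshared peaks of the replicates lie on different chromosomes was tested on 84 and 32 peaks and did not pass a permutation test (p = 0.69); chromosome II held 28.6% of those of replicate 1 and 15.6% of those of replicate 2.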
